A study of Mus musculus with 12 samples.

How the data were processed

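The populations of sorted splenic CD8+ T cells numbered 6 and were described by 12 samples, a gene expression and a TCR library for each treatment and subset. Per the labels' protocols, libraries were made with the Chromium Next GEM Single Cell 5′ kit and sequenced on a NextSeq with reads of 28 and 91 bases and an index of 8 bases. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 4.0.0 and the mouse build mm10. How doublets were treated is not given in the sources used here. No doublet caller was run, since no expression values per gene were used here. Cells with more than 1 TRB were left out as an alternative. They made up 15.8% of paired control and 17.6% of paired anti-CD137 Teff cells. In the same order they made up 7.19% and 23.8% in Tpex, and 3.16% and 4.92% in Tex.

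The deposited cell table gives, per cell, the count of UMIs, the count of genes with a UMI, the percent of UMIs from mitochondrial and from ribosomal protein genes, 2 cell cycle scores with a phase, and a cluster number from 0 to 8. Per the file headers these are columns of a Seurat object. Its values lay between 501 and 3998 genes per cell and at most 9.98 percent mitochondrial UMIs, as after filters by the authors. The lowest UMI count differed between libraries, with sharp lower ends in 3 of them. The deposited score columns and phases were not compared between treatments, because cells could not be thinned to 1 depth without counts per gene. Clusters were those the authors deposited. They are called by number, because gene lists fixed for naming them could not be used without gene values. No gene tests were run for the same reason.

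The deposited TCR table gives, per assembled contig, the chain, V and J segment, CDR3, and the count of UMIs and of reads. It held 192524 contigs of 97217 barcodes, with at most 2 TRA and 2 TRB chains per barcode. Contigs were joined to cells by library and barcode. A cell's TRA and TRB were those with the most UMIs. A clonotype was the pair of their nucleotide CDR3s in cells with both chains that were in the cell table, 64661 cells in all. The deposited clonotype numbers were not used across libraries: 15608 numbers recurred in at least 2 libraries, and 0 of these stood for the same receptor. Some V segments carry a combined name in the table and were kept as deposited. Positions of segments were taken from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, counted from 1.

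Each library was its own group of 1, so no test was run and no p-value is given. Shares have exact Clopper-Pearson 95% intervals from scipy 1.17.1, and differences have intervals built from those of both shares by Newcombe's square-and-add method. A share of 0 is given with the limit of 3 counts or, where named, with the exact interval. Expanded shares and clonotype counts were expected values after drawing 4471 cells, the paired cells of the smallest library, without replacement. Sharing between subsets used all paired cells. Pairing was checked as the share of other cells with the same TRB that carried the same TRA, averaged over paired cells whose TRB recurred in the library.

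V segments were compared where they reached 1% of paired cells in at least 1 of the 2 libraries of a subset, and named where the intervals did not overlap, up to 10 per direction and subset by ratio. Named clonotypes were the 3 largest of each library and the 5 largest found in all 3 subsets of a treatment. Clusters were named where they held at least 5% of any library. These rules were set before the data were examined. Tested on simulated Teff libraries with 19 segments and a fold of 1.5, the segment comparison recovered 100% of changed segments in 100 simulations and called 0.438% of unchanged ones. The simulation drew cells independently, with the TRBV shares and sizes of Teff libraries. In Tpex and Tex, cells of large clonotypes are not independent, so it gives no rate of false calls there. The thinning formula was tested against 200 random draws and differed by at most 1.07%.

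Alternatives fixed before the data were examined varied the definition of a clonotype, the cells and chains used, the size that counts as expanded, thinning, and the counting of clonotypes once. Others were added after seeing the data: bins of UMIs per cell with at least 20 cells in both libraries, cells with at least 5 TRB and 3 TRA UMIs, all TCR barcodes thinned to the smallest library, TRB segments counted once per TRB CDR3, and leaving out the 10 largest clonotypes. Values over UMI bins are means of the shares per bin, each weighted by its cells in both libraries. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.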

Results

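Splenic CD8+ T cells of wild-type C57BL/6 mice were profiled after 14 days of treatment with an antibody to CD137 (4-1BB, a costimulatory receptor of activated T cells) or with a control immunoglobulin (Ig). Clone 3H3 was injected at 10 µg into 5 mice and clone HRPN, the control, at 100 µg into 10 mice, on 2 days a week. Cells with high CD44, a marker of antigen experience, were sorted into 3 subsets. Effector cells (Teff) lacked PD1, an inhibitory receptor that marks chronically stimulated T cells. Precursor exhausted cells (Tpex) carried PD1 and Slamf6 but not Tim3, and exhausted cells (Tex) carried PD1 and Tim3 but not Slamf6. Each treatment and subset gave 1 library of 5′ gene expression and 1 of T cell receptor (TCR) chains, so that 12 samples describe 6 populations. Cells were not tied to single mice, and no difference between treatments has a replicate check. All intervals are exact 95% binomial intervals, or intervals of a difference built from them, and cover counting error only. Cells of a clonotype are not independent draws.

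The deposited cell table held 100540 cells. Teff libraries had 25912 cells in the control and 28028 with anti-CD137, Tpex libraries 12871 and 13209, and Tex libraries 10623 and 9897. The median count of unique molecular identifiers (UMIs) per cell was similar in the Teff libraries, at 4176 in the control and 4035 with anti-CD137. It was lower with anti-CD137 in Tpex (1950 against 4729) and in Tex (3473 against 5619). The lowest UMI count of any cell was 2558 in the control Tpex library, 1472 in the anti-CD137 Tpex library and 1840 in the anti-CD137 Tex library, and between 586 and 653 in the other libraries. Total UMIs ranged from 31252414 in the anti-CD137 Tpex library to 126261864 in the anti-CD137 Teff library. The median share of ribosomal protein UMIs fell across the subsets in both treatments, from 37.0% in control Teff through 25.1% in Tpex to 18.1% in Tex. With anti-CD137 it was 24.3% in Tpex and 18.1% in Tex.

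The first comparison asked in which transcriptional clusters the cells of each subset lay with and without anti-CD137. The treatments parted most in Tex. In the control, 86.9% of Tex cells (86.2 to 87.5%) were in cluster 3 and 8.89% (8.35 to 9.44%) in cluster 4. With anti-CD137, 19.2% were in cluster 3 and 79.8% (79.0 to 80.6%) in cluster 4. The cluster 4 share was thus 70.9 percentage points higher with anti-CD137 (69.9 to 71.8). Clusters 3 and 4 held mainly Tex cells, with 95.4% and 98.7% of their cells from the Tex libraries. Of the cells in cluster 3 or 4, each of the 10 largest Tex clonotypes with anti-CD137 had 71.6 to 90.6% in cluster 4, and each of the 10 largest in the control 2.13 to 14.7%.

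The cluster 4 share fell as the UMI count of a cell rose above 2000, from 39.5% at 2000 to 2500 UMIs to 0.191% above 10000 in the control, and from 93.8% to 16.9% with anti-CD137. The libraries differed in each UMI bin that held cells of both. Averaged over these bins, each weighted by its cells in both libraries, the cluster 4 share was 70.0% with anti-CD137 and 13.3% in the control. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

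**Figure D1:**
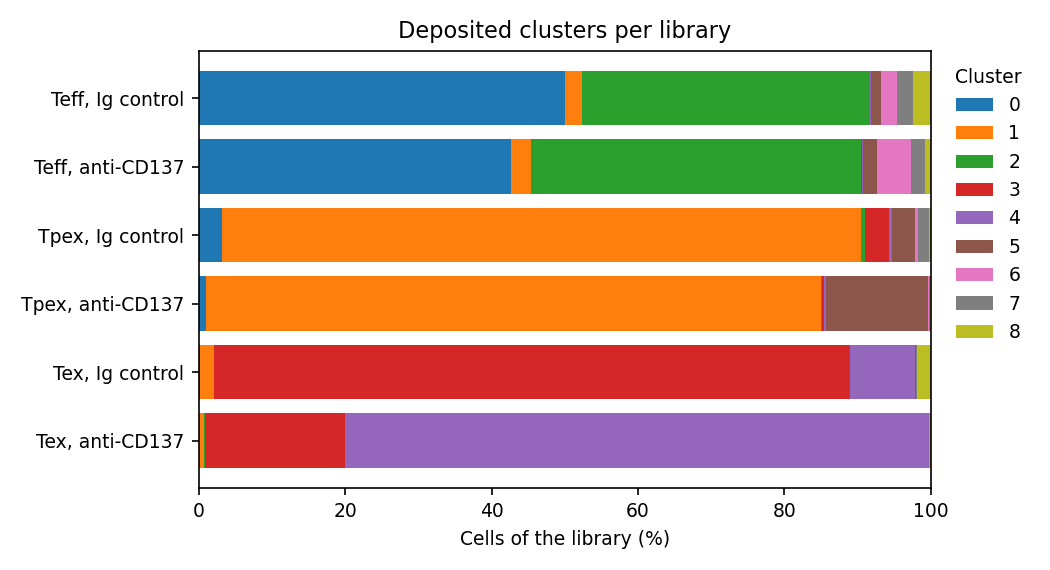
Horizontal bars give the percent of cells of each of the 6 libraries in the deposited clusters 0 to 8, marked by colour. Cluster 3 fills 86.9% of the control Tex bar, and cluster 4 fills 79.8% of the anti-CD137 Tex bar.

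**Figure D2:**
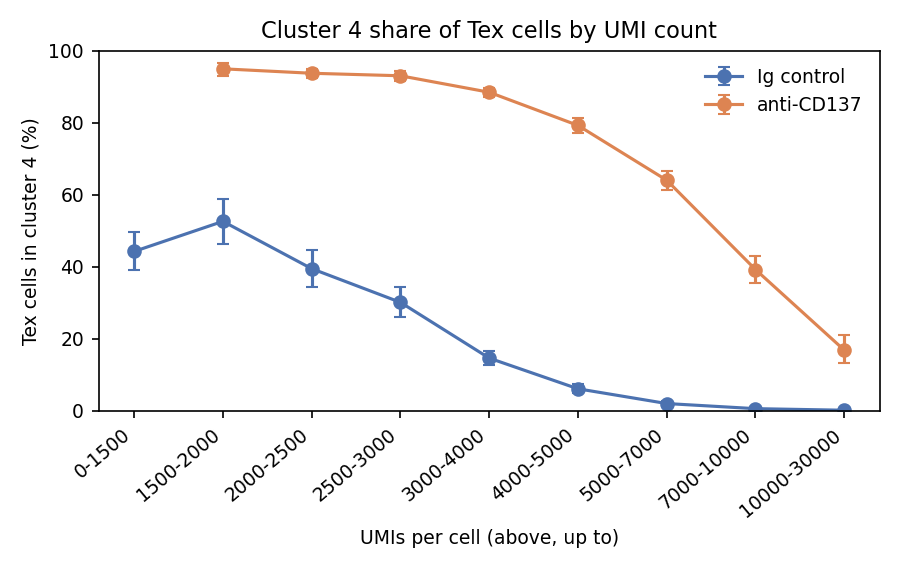
Points give the percent of Tex cells in cluster 4 (vertical axis) by bins of UMIs per cell (horizontal axis) for the 2 Tex libraries, with exact 95% intervals as bars. The anti-CD137 points lie above the control points in each bin with cells of both, for example 88.5% against 14.7% at 3000 to 4000 UMIs.

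Tpex cells lay mostly in cluster 1 in both treatments, at 87.4% in the control (86.8 to 88.0%) and 83.9% with anti-CD137 (83.3 to 84.6%). Cluster 5 held more of them with anti-CD137, 13.9% (13.3 to 14.5%) against 3.17% (2.87 to 3.49%), and cluster 3 fewer, 0.363% against 3.29%. The cluster 3 difference depended on the UMI count. From 2500 to 7000 UMIs its share was not lower with anti-CD137, with 6.62% against 2.37% at 5000 to 7000. Above 7000 UMIs it was lower, with 2.94% against 8.65% at 7000 to 10000. Counted once per clonotype and cluster, the cluster 1 share no longer fell and differed by 0.166 percentage points. The cluster 5 share rose with UMI counts above 3000 in both Tpex libraries. It was averaged over the UMI bins that held cells of both libraries, each weighted by its cells in both. This gave 35.4% with anti-CD137 and 2.83% in the control, and a cluster 1 share of 60.4% against 87.9%. These are weighted means, not shares of all cells in the bins. Those bins held 3439 anti-CD137 cells, and most cells of that library had fewer UMIs than any control Tpex cell.

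Teff cells lay in clusters 0 and 2 in both treatments. Cluster 0 held 42.6% of them with anti-CD137 and more in the control, a difference of -7.43 percentage points (-8.27 to -6.58). Cluster 2 held 39.4% in the control and 45.1% with anti-CD137, a difference of 5.64 (4.81 to 6.48). Among cells with a paired TCR, the differences were -4.38 and 2.84. With these cells counted once per clonotype and cluster, they were -3.62 and 3.25. Cluster 6 was named only after its values were seen, since it held under 5% of every library. It took 2.20% of control Teff cells (2.02 to 2.38%) and 4.63% of anti-CD137 Teff cells (4.39 to 4.89%).

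The next comparisons rest on the TCR chains, which mark cells that descend from a common ancestor. A chain was found in 81.1% of control and 88.0% of anti-CD137 Teff cells. It was found in 88.5% and 45.9% of Tpex cells, and in 81.9% and 59.7% of Tex cells. Both an alpha chain (TRA) and a beta chain (TRB) were found in 67.2% and 72.2% of Teff, 78.0% and 33.8% of Tpex and 73.2% and 47.7% of Tex cells, the control first. Among Teff cells above the median UMI count of their library, the order turned, with 79.9% paired with anti-CD137 and 81.8% in the control. In the anti-CD137 Tpex library, 66.9% of the barcodes with a TCR chain were not in the cell table, against 14.5% in the control Tpex library.

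Chains were paired less cleanly in the anti-CD137 Tpex library than in the control. Among its paired cells whose TRB recurred in the library, a further cell with that TRB carried the same TRA in 41.9% of cases. Few Teff cells had a recurring TRB, and there the value was 35.5% in the control and 49.0% with anti-CD137. It was 91.8% in the control Tpex library, 95.8% in the control Tex library and 89.9% in the anti-CD137 Tex library. Of 98 TRB chains found in at least 5 paired anti-CD137 Tpex cells, 37 had no TRA that was carried by at least 50% of their cells, against 0 of 221 in the control. A TRBV1 chain with the CDR3 (the hypervariable loop that contacts antigen) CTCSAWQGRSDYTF, for example, was found in 10 cells with 9 different TRA chains. Expanded shares and sharing with Tpex are therefore also given from TRB alone, and other values that use pairs of anti-CD137 Tpex cells rest on both chains.

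Clonal expansion was compared as the share of cells in clonotypes of at least 2 cells, after thinning each library to the 4471 paired cells of the smallest. Expansion was rare in Teff, common in Tpex and most common in Tex in both treatments. In Tex, 89.4% of control cells (88.4 to 90.2%) and 81.8% of anti-CD137 cells (80.7 to 83.0%) were in expanded clonotypes, a difference of -7.52 percentage points (-8.98 to -6.05). It was -4.77 by TRB alone and -12.4 for clonotypes of at least 5 cells. Each 100 thinned Tex cells held 18.3 clonotypes in the control and 28.4 with anti-CD137. The 10 largest Tex clonotypes took 42.0% of control cells (40.9 to 43.1%) and 21.6% of anti-CD137 cells (20.5 to 22.8%).

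In Tpex, the direction depended on the definition of a clonotype. By both chains, 48.0% of control cells (46.6 to 49.5%) and 32.7% of anti-CD137 cells (31.3 to 34.1%) were in expanded clonotypes. By TRB alone, the shares were 50.3% (48.8 to 51.7%) and 63.1% (61.6 to 64.5%). In Teff, 1.26% of control cells (0.967 to 1.65%) and 2.12% of anti-CD137 cells (1.72 to 2.59%) were in expanded clonotypes by both chains. By TRB alone these were 3.50% and 3.28%, with overlapping intervals.

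**Figure D3:**
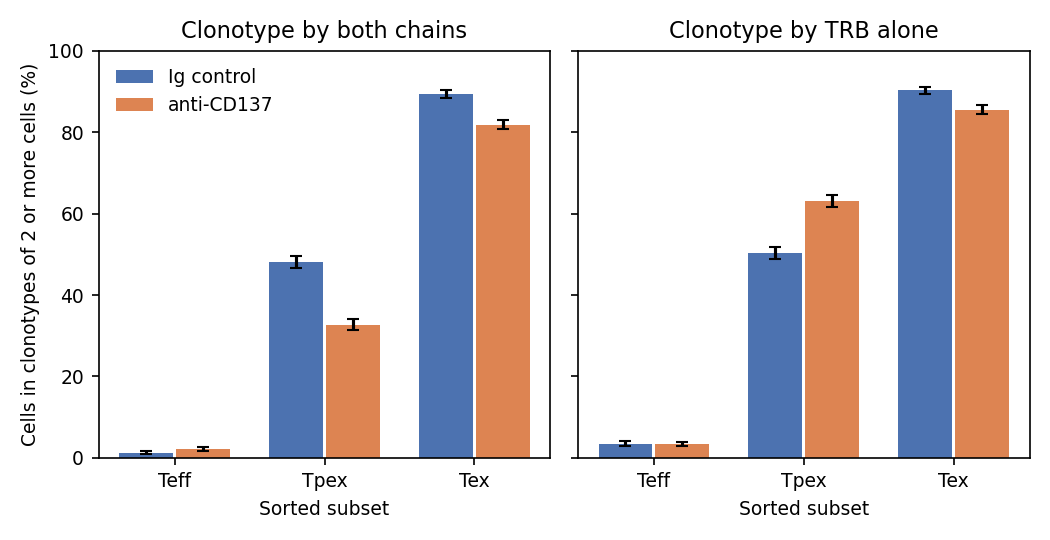
Bars give the percent of cells in clonotypes of at least 2 cells for each subset and treatment, after thinning to 4471 cells, with exact 95% intervals. By both chains (left) the anti-CD137 Tpex bar stands at 32.7% and the control at 48.0%, and by TRB alone (right) at 63.1% and 50.3%.

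The largest clonotypes of the control were large in both PD1+ subsets. A receptor of TRBV2 with the CDR3 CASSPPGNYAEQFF and TRAV6-7-DV9 with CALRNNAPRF took 869 Tpex cells (8.65%), 762 Tex cells (9.80%) and 2 Teff cells. A receptor of TRBV5 with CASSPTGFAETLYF and TRAV12-3 with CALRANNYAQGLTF took 797 Tpex and 702 Tex cells. A further TRBV5 receptor, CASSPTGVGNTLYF with TRAV12D-3, took 183 Tpex and 379 Tex cells. The TRBV5 receptor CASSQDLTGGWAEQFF with TRAV16N was large in Tex, with 589 cells, and had 25 Tpex cells.

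With anti-CD137 the largest clonotypes of Tpex and Tex were smaller. The largest in Tex joined TRBV1 with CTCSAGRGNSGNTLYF to TRAV13-2 and took 213 Tex cells (4.52%) and 1 Tpex cell. The next joined TRBV29 with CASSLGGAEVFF to TRAV6N-7, with 128 Tex and 5 Tpex cells. The receptor of TRBV17 with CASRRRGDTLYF and TRAV3N-3 was found in all 3 subsets, with 116 Tex, 46 Tpex and 10 Teff cells. Its TRB was also at 390 barcodes of the anti-CD137 Tpex library outside the cell table, the library in which chains were poorly paired. This TRB itself had few partners, with 3 TRA chains in the 48 paired cells of that library. The largest Teff clonotypes had 13 cells in the control and 23 with anti-CD137. Only 3 clonotypes were found in both treatments, and 6 of the 9 pairs of a control and an anti-CD137 library shared none. Counted by cells, 3.05% of control Tex cells (2.68 to 3.45%) had a clonotype found in anti-CD137 Tex. Of these 237 cells, 236 carried the receptor with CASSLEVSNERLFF, found in 1 anti-CD137 Tex cell.

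Sharing of clonotypes between subsets was compared as the share of cells of 1 subset whose clonotype was also found in another. In the control, 78.6% of Tex cells (77.7 to 79.5%) had a clonotype found in Tpex, and with anti-CD137 42.9% (41.5 to 44.4%). In the other direction, 37.9% of control Tpex cells (37.0 to 38.9%) had a clonotype found in Tex, 25.9 percentage points more than with anti-CD137. The difference for Tex cells found in Tpex was -35.7 percentage points (-37.4 to -34.0). By TRB alone it was -15.5, from 81.4% and 65.8%, and the difference for Tpex cells found in Tex was -13.0, from 39.4% and 26.4%. By both chains, as a share of clonotypes in place of cells, the difference for Tpex found in Tex was -2.41. More paired Tpex cells were searched in the control (10041) than with anti-CD137 (4471). Thinned to 4471 cells per library, the difference by both chains was -28.1 for Tex cells found in Tpex and -23.2 in the other direction. Values by TRB alone were not thinned.

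Sharing with Teff was lower. As a background, sharing across treatments, between different mice, reached at most 3.05% of the cells of a library, for control Tex cells found in anti-CD137 Tex. Teff held the clonotypes of 11.2% of anti-CD137 Tex cells, a difference from the control of -0.853 percentage points (-2.01 to 0.324). After thinning, the shares were 5.97% with anti-CD137 and 5.11% in the control. Without the largest clonotype of each library the control had 2.49% and anti-CD137 11.7%, since 2 Teff cells carried the receptor of 762 control Tex cells. Other settings moved the difference the other way, to -4.26 (-5.22 to -3.28) when at least 2 Teff cells were asked for, so that its direction depended on the setting. For Tpex cells the shares were 10.9% and 4.47% by both chains, 13.9% and 11.2% by TRB alone, and 2.43% and 3.48% by both chains without the largest clonotype. Among Teff cells, 0.299% (0.223 to 0.391%) in the control and 0.771% (0.655 to 0.901%) with anti-CD137 had a clonotype found in Tex. A clonotype found in Tpex was carried by 0.706% and 0.717% of Teff cells, and by 1.62% and 1.54% by TRB alone, with intervals of the difference that include 0. Among cells with at least 5 TRB and 3 TRA UMIs, the difference was -0.338 percentage points (-0.547 to -0.139).

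**Figure D4:**
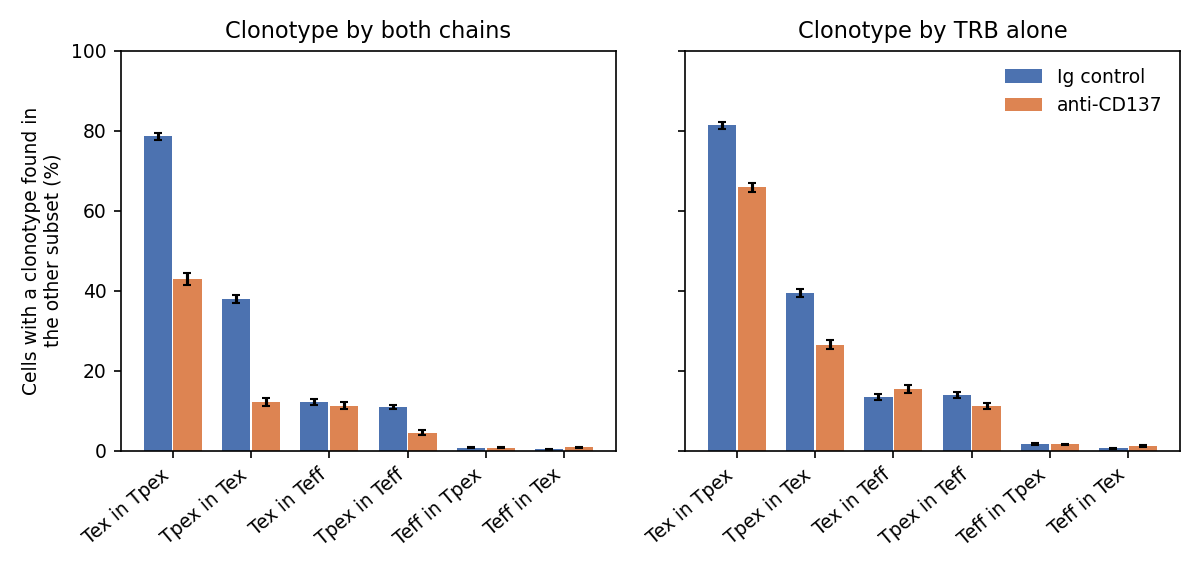
Bars give the percent of cells of the first subset whose clonotype was found in the second, per treatment, with exact 95% intervals, by both chains (left) and by TRB alone (right). Libraries were not thinned to equal size. The Tex in Tpex bars stand at 78.6% in the control and 42.9% with anti-CD137 by both chains, and at 81.4% and 65.8% by TRB alone.

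Teff cells that shared a clonotype with a PD1+ subset lay outside the main Teff clusters. Of 137 such control cells, 94.9% (89.8 to 97.9%) were in clusters other than 0 and 2, and of 195 anti-CD137 cells 95.4% (91.4 to 97.9%). Teff cells that shared none were outside clusters 0 and 2 in 9.59% and 11.0% of cases. Clonotype size went with this as well. All expanded Teff cells were outside clusters 0 and 2 in 32.5% and 74.1% of cases, and cells of clonotypes of 1 cell in 9.41% and 8.86%. Sharing and clonotype size were not separated here. Cluster 6 held 48.9% and 66.7% of the sharing Teff cells, and cluster 1, where most Tpex cells lay, 43.1% and 26.2%. Among control Tpex cells, 5.65% of those with a clonotype found in Tex and 2.63% of the others were in cluster 3 or 4. With anti-CD137 these were 2.23% and 1.04%, and among clonotypes of at least 3 cells the order turned, with 2.47% and 3.33%. In the control the difference among such clonotypes was 1.33 percentage points, with an interval that includes 0 (-0.167 to 2.68).

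V segments, the gene segments that encode the first part of each chain, were used in similar shares in the Teff libraries. Of 61 segments at or above 1% of paired cells, 0 had intervals that did not overlap, though the interval of the difference excluded 0 for some, as for TRBV13-2 (0.0273 to 0.437 percentage points). In Tpex 33 of 60 and in Tex 44 of 58 did. When each clonotype was counted once, 10 of the 33 and 1 of the 44 still lay apart in the same direction. Clonotypes are fewer than cells and their intervals wider, so the lost calls do not show that clonotype size made the differences. TRBV17 in Tex lay apart in the opposite direction, with 3.18% of anti-CD137 and 1.53% of control cells, but 1.22% and 3.39% of clonotypes. The segment in Tex that kept its direction was TRAV9N-3, with 5.55% and 4.15% of cells and 4.71% and 2.05% of clonotypes. Both were named after their values were seen. Positions of segments are on mm10.

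In Tpex, TRBV29 (chromosome 6, 41271394 to 41271881) was used by 11.1% of anti-CD137 cells and 5.14% of control cells, and by 10.2% and 6.15% of clonotypes. TRBV15 (chromosome 6, 41141188 to 41141658) was used by 4.67% and 1.89% of cells, and by 4.43% and 2.80% of clonotypes. Counted once per TRB CDR3, TRBV29 and TRBV15 remained higher by 3.44 and 1.46 percentage points. The TRA segments TRAV7D-3 (chromosome 14, 52744249 to 52744840; 1.39% against 0.319%) and TRAV8N-2 (chromosome 14, 53345890 to 53346424; 3.04% against 1.68%) were also higher with anti-CD137. TRBV2, TRBV16, TRAV14N-2, TRAV16, TRAV16D-DV11 and TRAV9-4 were lower by cells and by clonotypes, of which TRBV16 was named after its values were seen. TRAV9-4 (chromosome 14, 53676141 to 53676630) had 0.425% against 1.12% of cells, and TRBV2 1.44% against 2.40% of clonotypes.

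Some differences in V segments by cells rested in part on large clonotypes. TRBV5 (chromosome 6, 41062332 to 41062803) was used by 14.1% of control and 3.89% of anti-CD137 Tpex cells, but by 3.84% and 3.92% of clonotypes. In Tex it was used by 27.5% and 8.03% of cells, and by 6.87% and 7.07% of clonotypes. TRBV2 (chromosome 6, 41047340 to 41047995) was used by 12.9% of control and 0.975% of anti-CD137 Tex cells, with 762 of the control cells from 1 clonotype. Of the segments higher in anti-CD137 Tex, TRAV3N-3 (chromosome 14, 53283585 to 53284175; 9.94% against 1.62%) had 116 of its 469 cells in its largest clonotype. TRAV13-2 (chromosome 14, 53634829 to 53635399; 4.79% against 0.566%) had 213, and was used by fewer clonotypes with anti-CD137 (0.532% against 1.16%), with an interval of the difference that includes 0 (-1.50 to 0.152 percentage points).

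Invariant T cells were rare in the sorts. Receptors of invariant natural killer T cells (TRAV11 or TRAV11D with TRAJ18) were found in 4 of 17420 control and 16 of 20234 anti-CD137 Teff cells, 0.0230% (0.00626 to 0.0588%) and 0.0791% (0.0452 to 0.128%). They were found in 3 of 10041 control and 4 of 4471 anti-CD137 Tpex cells, 0.0299% and 0.0895%. In Tex they were found in 0 of 7778 and 0 of 4717 cells. The limit of 3 counts allows shares of up to 0.0386% and 0.0636% there. Receptors of mucosal-associated invariant T cells (TRAV1 with TRAJ33) were found in 2 control and 7 anti-CD137 Teff cells. The mean TRB CDR3 length was 13.9 amino acids in each Teff library, 13.9 in control and 14.0 in anti-CD137 Tpex, and 14.2 and 14.1 in Tex. These differences were small beside the spread over cells (SD at least 1.31 in each library). In Tex the order turned when each clonotype was counted once, with 13.86 in the control and 13.90 with anti-CD137.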

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

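Clonotypes by TRB alone were fixed as a definition before the data were examined, but their use as a test, and the tests by matched UMI bins, barcode overlap, cells of cluster 3 or 4, libraries per group and without the 10 largest clonotypes, were chosen after the results were seen. The share of cells in expanded clonotypes moved in opposite directions between subsets, by 0.853 percentage points in Teff, -15.4 in Tpex and -7.52 in Tex (anti-CD137 minus control, by both chains). The share of cells with both TCR chains did so too, by 4.96 in Teff, -44.2 in Tpex and -25.6 in Tex. The sign within single subsets depended on the setting. By TRB alone the expanded share differed by -0.212 in Teff (-0.973 to 0.563), 12.8 in Tpex and -4.77 in Tex. The paired share in Teff differed by -1.91 above the median UMI count and by 3.05 in matched UMI bins. Neither difference between subsets was tested, as each rests on 1 library per group. Barcodes with a TCR chain but outside the cell table are not used in the main comparisons. They made up 4.14% of the TCR barcodes of anti-CD137 Teff, 66.9% of Tpex and 35.2% of Tex, above the control libraries at 3.21%, 14.5% and 3.16%.

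Few cells of the anti-CD137 Tpex library had a TCR. Among the 3439 of its 13209 cells in UMI bins shared with the control, fewer gene expression UMIs do not account for all of this. The difference in the share of cells with a chain was still -36.1 percentage points. These bins do not match the depth of the TCR libraries, which had 14078543 reads with anti-CD137 and 59104451 in the control. Median TRB UMIs per cell were 6 and 15, so that a lower TCR depth stays open. For the other 9770 cells no control cells had as few UMIs, so that depth and treatment cannot be told apart there. A TCR library made from other cells is argued against by the barcodes: 6065 were in the cell table of the same library, and at most 719 in that of any other. No biological explanation was tested.

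Clonotypes looked smaller with anti-CD137 in Tpex and Tex. In Tpex, chains of different cells taken as a pair may account for this, since the difference in expanded share was 12.8 percentage points by TRB alone. A TRB that reached other cells would raise the value by TRB alone, so that neither value settles the direction. In Tex, wrong pairs and a few very large control clonotypes are argued against as the whole cause, since the difference was -4.77 by TRB alone and -7.25 without the 10 largest clonotypes. An effect of the treatment and a difference between the mice of each pool stay open and untested. The number of mice, 10 in the control and 5 with anti-CD137, was not varied, so the size of its effect stays open too. At equal cell numbers, a pool of more mice holds more repertoires, which by itself would lower the control's expanded share, not raise it.

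Tex cells lay in cluster 4 with anti-CD137 and in cluster 3 in the control. Fewer UMIs per cell do not account for the whole difference, which stayed at 56.7 percentage points over matched UMI bins. A shift shared by all anti-CD137 libraries stays open: among cells of cluster 3 or 4, the cluster 4 share differed by -28.4 points (-54.0 to 1.63) in Teff, on 15 control cells, and by 32.2 (21.0 to 43.8) in Tpex, at unequal UMI counts. With 1 library per treatment and subset, an effect of the treatment and a property of single libraries cannot be told apart.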

How the results depend on the processing

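All values here are differences, anti-CD137 minus control, in percentage points unless named otherwise, and "Tex in Tpex" means Tex cells with a clonotype found in Tpex. Of 194 alternative values of the comparisons, 170 kept the sign and 24 changed it. Matched UMI bins, cells with at least 5 TRB and 3 TRA UMIs, all TCR barcodes after thinning, TRB segments once per CDR3 and leaving out the 10 largest clonotypes were chosen after seeing the data. The deposited clonotype numbers and another cluster column were not run, since the first do not hold across libraries and only 1 cluster column was used here. The sign of the Tex comparisons (expanded share -12.4 to -4.77, clonotypes per 100 cells 7.83 to 14.6, Tex in Tpex -46.8 to -15.5, cluster 4 50.8 to 70.9) held under every alternative run. By TRB alone, the expanded share was -0.212 in Teff, 12.8 in Tpex and -4.77 in Tex, and clonotypes per 100 cells -0.0414, -2.22 and 7.83. Sharing by TRB alone was -15.5 for Tex in Tpex, -13.0 for Tpex in Tex, 1.98 for Tex in Teff and -2.72 for Tpex in Teff. By amino acid pairs, Tex in Tpex was -33.4. With all TCR barcodes, the expanded share was -31.0 in Tpex and -12.4 in Tex, clonotypes per 100 cells 28.0 and 14.6, Tex in Tpex -26.4 and Tpex in Tex -27.7. Thinned as well, Tex in Tpex was -33.1, Tex in Teff 0.723 and Tpex in Teff -2.61. With chains of at least 2 UMIs, Tpex had -11.1 for the expanded share and 15.1 clonotypes per 100 cells. Cells with at least 5 TRB and 3 TRA UMIs, thinned to 1553, gave Tpex -4.04 and 9.10 by both chains, and 7.33 and 2.004 by TRB alone. Sharing in those cells was, by both chains and by TRB alone, -46.8 and -43.3 for Tex in Tpex, -22.7 and -18.3 for Tpex in Tex, and -4.49 and -2.38 for Tpex in Teff. Tex in Teff was -2.76 by both chains, Teff in Tpex -0.338 and -0.559 with intervals that exclude 0 (-0.547 to -0.139 and -0.845 to -0.283), and Teff in Tex 0.302 and 0.276. Counted as expanded from 3 cells, Tpex had -21.1 and Tex -9.82, and from 5 cells Teff had 0.213, Tpex -22.6 and Tex -12.4. Without thinning, the expanded share was -23.7 in Tpex and -9.65 in Tex, and clonotypes per 100 cells 25.9 and 13.5. Without the largest clonotype, Tpex had 14.0 clonotypes per 100 cells more, and sharing was -38.7 for Tex in Tpex, -20.9 for Tpex in Tex, 9.23 for Tex in Teff and 1.05 for Tpex in Teff. Without the 10 largest, Tpex had 7.19 per 100 cells and -7.23 for the expanded share, and sharing was -27.3, -11.1, 7.58 and 0.229 in the same order. Tex in Teff and Tpex in Teff turned because single control clonotypes with few Teff cells carried much of that sharing. Sharing thinned to the smallest library was -28.1, -23.2, 0.856 and -2.41 in that order, and 0.238 for Teff in Tpex. With at least 2 cells in the library searched, Tex in Tpex was -45.6, Tpex in Tex -23.7 and Tex in Teff -4.26. As shares of clonotypes, the values were -25.5, -2.41, 2.56 and 0.323 in the earlier order, 0.175 for Teff in Tex and -0.136 for Teff in Tpex (-0.272 to -0.00521). Among cells with a paired TCR, cluster 0 in Teff was -4.38, cluster 2 in Teff 2.84, cluster 1 in Tpex -5.01 and cluster 4 in Tex 68.6. Above the median UMI count, cluster 0 in Teff was -8.40, clusters 1 and 5 in Tpex -5.96 and 14.8, and clusters 3 and 4 in Tex -66.2 and 65.9. The paired TCR share there was -1.91 in Teff, -37.4 in Tpex and -20.1 in Tex. With clonotypes once per cluster, clusters 0 and 2 in Teff were -3.62 and 3.25, clusters 1 and 5 in Tpex 0.166 and 8.56, and clusters 3 and 4 in Tex -44.1 and 50.8. In matched UMI bins, clusters 1 and 5 in Tpex were -27.5 and 32.6, and clusters 3 and 4 in Tex -53.0 and 56.7. The paired TCR share in those bins was 3.05 in Teff, -31.1 in Tpex and -23.8 in Tex. CDR3 length with each clonotype once was 0.110 amino acids in Tpex and 0.0374 in Tex. The excess in cluster 3 or 4 of Tpex cells with a clonotype in Tex was, for clonotypes of at least 3 cells, -0.856 with anti-CD137 and 1.33 in the control (-0.167 to 2.68). Of 80 alternative values of V segments, 69 kept the sign. With each clonotype once, signs turned among the segments named by the rule for TRBV5 (0.0813 in Tpex, 0.203 in Tex), in Tpex for TRAV12-3 (0.593), TRAV12D-3 (0.146) and TRAV6-7-DV9 (0.249), and in Tex for TRAV10D (0.328), TRAV13-2 (-0.627) and TRAV13D-4 (0.0234). The intervals of these turned differences include 0, except for TRAV12-3 (0.0746 to 1.15), so the others show a lost difference rather than a reversed one. Segments outside the rule turned too, such as TRBV17 (-2.17), TRBV1 (-1.76) and TRBV19 (-3.02) in Tex, of which TRBV1 had an interval that includes 0 (-3.74 to 0.166). Once per TRB CDR3, TRBV5 had 0.206 in Tpex and 0.382 in Tex, and with segments summed by stem TRAV9N-4 in Tex had -0.263. Except where a cause is given, the cause was not tested. The anti-CD137 Tpex library set the depth of thinning, with 4471 paired cells.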

Other observations

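All comparisons in this part were chosen after the data were seen. The receptors of Tex differed from those of Teff in the same way in both treatments for 4 of 20 TRBV segments, counted once per clonotype. TRBV19 was used by 12.2% of control Tex and 5.80% of control Teff clonotypes, and by 9.20% and 5.80% with anti-CD137. TRBV5 was used by 6.87% and 3.98% in the control and by 7.07% and 3.81% with anti-CD137. TRBV12-2 and TRBV16 were lower in Tex, TRBV12-2 with 4.46% against 7.53% in the control and 4.03% against 7.30% with anti-CD137. In each of these the intervals of Tex and Teff did not overlap.

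TRBV5 chains whose CDR3 opens with CASSPTG, a start taken from the largest control clonotypes, made up 9.80% of control Tpex cells and 13.9% of control Tex cells, from 4 clonotypes in each. This start was chosen because it was common in control cells, so their cell shares are not compared with anti-CD137. Counted once per TRBV5 clonotype the exact intervals overlapped. In Tpex there were 4 of 206 in the control (0.532 to 4.90%) and 0 of 139 with anti-CD137 (0 to 2.62%). In Tex there were 4 of 77 in the control (1.43 to 12.8%) and 0 of 93 with anti-CD137 (0 to 3.89%). In Teff such chains were found in 11 control and 10 anti-CD137 cells, each of another clonotype.

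Teff cells of cluster 6 were more often in expanded clonotypes than those of cluster 2, but clusters 1, 3 and 4 held them too. In cluster 6, 33.5% of paired control cells (28.7 to 38.6%) and 53.4% of anti-CD137 cells were in expanded clonotypes of all paired cells. In cluster 2 these were 1.98% and 1.56%, and in cluster 1 12.6% and 26.2%. With anti-CD137 they were 59.1% of 44 cells in cluster 3 and 76.5% of 17 in cluster 4. Cluster 6 held 18.8% of all expanded control Teff cells and 50.2% of those with anti-CD137, and cluster 0 held 43.3% and 9.30%. The control Tpex cells that lay in cluster 3 had a mean G2M score of 0.578 (SD 0.411 over cells), against -0.0565 (SD 0.153) in cluster 1, at a median of 9136 against 4615 UMIs.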
